A study of Mus musculus with 6 samples.

How the data were processed

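RNA was measured by sequencing in 6 libraries of CD71+Ter119+ erythroid cells, sorted from mouse fetal liver at embryonic day 13.5. CD71 is the transferrin receptor and Ter119 a red cell lineage antigen. The labels place 3 libraries in the Tfam WT group and 3 in the Tfam KO group, numbered 1 to 3 in each. Per the labels' protocols, libraries came from total RNA with a TruSeq kit and were read on a NextSeq 500. The labels give no litter, sex, batch or Cre driver and do not say whether the replicates were separate embryos, so p-values measure only the spread between these libraries.

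The deposited table holds RPKM values, read numbers scaled to transcript length and to the total of mapped reads. TopHat and Cufflinks with build mm9 made the RPKM values, per the submitters' processing notes, and the versions, the annotation and any strand setting are not given in the sources used here. RPKM divides by an annotated length and by a library total, so a library in which long transcripts yield fewer reads shifts genes according to their length. The table has 23119 rows. Of these, 25 carry a number in place of a gene name and were left out, with a mean of 0.158% of the RPKM sum. Another 492 rows join several gene names, so their value cannot be assigned to a single gene. Among tested rows, 80 gene names stand on more than 1 row (163 rows), and each row was tested separately. A named gene or list member found on more than 1 row, as were 12 list members, was represented by the row with the highest mean RPKM. Gata1 is such a gene. Klf1 shares its row with Dnase2a, Itga2b with Gpatch8, and the macrophage marker Cd68 with the translation factor Eif4a1. In all libraries 7231 rows are listed at 0, among them the adult alpha and beta globins and Hmgcs1, a gene that proliferating cells use, so a listed 0 can be a failed estimate. Reads from paralogs such as histone genes and ribosomal protein genes could be split between copies. No row carried the names searched for mRNAs encoded by mitochondrial DNA, so these were not analysed here.

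Read depth is unknown in absolute terms. Ratios of RPKM values below 0.05 between libraries cluster where whole reads would put them, which gave depths relative to WT replicate 2 of 88.9% for WT replicate 1, 93.0% for KO replicate 1, 84.4% for KO replicate 2 and 79.7% for KO replicate 3. These ratios lay on whole-read steps, within 0.03 on the log2 scale, for 72.8%, 39.8%, 72.1% and 75.4% of the rows compared. The depth of WT replicate 3 was not resolved, because 16.0% of its ratios lay on such steps against 9.5% for evenly spread values. No counts were available for intervals on single values.

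The test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with a mean-variance trend, no block, and Benjamini-Hochberg adjustment at 0.05. The 8302 rows with a mean RPKM of at least 1 over the 6 libraries were tested, 334 of them naming several genes and 139 naming small RNAs. Fold changes are on the log2(RPKM + 1) scale, which understates changes of low genes. Tfam was also compared with an exact two-sided permutation test, whose smallest possible p for 3 against 3 is 0.1. Of 50 gene lists, 44 had at least 3 tested members and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 44 lists. Camera with an estimated correlation and fry were run as alternatives. Intervals are 95% intervals from the limma fit. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

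The lists, the marker genes, the tests, the alternatives and the rule for named genes were chosen before the data were examined, unless stated otherwise. The rule names Tfam, then up to 8 genes per direction past the threshold with a mean RPKM of at least 5 and no overlap between groups, then the leading members of lists with a member past the threshold over all genes. No gene passed, so those parts name none. It also names every globin gene, mitochondrial DNA-encoded mRNAs, and Gata1, Klf1, Bcl11a, Alas2, Tfrc, Slc25a37, Ppargc1a, Bdh1, Hdac1, Atf4, Ddit3, Cdkn1a, Bnip3l and Kit, and a gene that is not reported here. All other genes in the text were chosen after their values were seen.

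The labels number the replicates alike in both groups. Deviations from the group means correlated at 0.46 between the libraries numbered 1, at 0.17 between those numbered 2 and at 0.53 between those numbered 3. Each was above 0.1, so by the rule fixed for this check the numbers were taken to pair the libraries, although WT replicate 2 correlated more with KO replicate 1 (0.40). The pairing comes from this check, not from a label.

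The test was checked on simulated values drawn from the means and spreads of the 8302 genes, with 200 genes changed. For KO versus WT it recovered 50% of changes of 1 on the log2 scale and 83% of changes of 2, with 6 false calls among 139. A shifted list was called and 0 of 40 unshifted lists were. The simulated genes varied independently, so this check does not cover correlated genes. Each gene also had the same spread in every simulated library. In the data the SD of the deviation from the mean of all libraries was 0.61 in WT replicate 3 and 0.23 to 0.32 in the others. The recovered shares therefore do not give the power of the real comparison. Transcript length and GC content for the technical checks came from the longest GENCODE vM21 transcript of each symbol and covered 99.5% of tested rows. That annotation is of another build than mm9, so no coordinates are printed. Alternatives covered the replicate block, the pseudocount, the filter, the scaling, the variance model, a minimum fold change, the set test and each library left out. Removal of the length and GC trend with splines of 4 degrees of freedom, omission of both libraries numbered 3, omission of small RNA rows, and an estimated correlation combined with the trend removal or the omission of WT replicate 3 were added after seeing the data.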

Results

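The series profiled erythroid cells of the fetal liver, sorted as CD71+Ter119+ at embryonic day 13.5, from mice labelled Tfam WT (n = 3) or Tfam KO (n = 3). Tfam encodes a mitochondrial transcription factor that packages mitochondrial DNA and acts in its transcription. The comparison asks which transcripts of maturing erythroblasts differ when the gene is deleted. RPKM sums were 423263 to 535933 in 5 libraries and 815524 in WT replicate 3. Log2 values of WT replicate 3 correlated at 0.930 to 0.962 across genes with the other libraries, which correlated with each other at 0.973 or more. WT replicate 3 also differed by transcript length. The median deviation from the mean of all libraries was 0.65 on the log2 scale for the 1655 genes with the shortest transcripts and -0.51 for the 1649 with the longest. Malat1, a long nuclear RNA, was at 46.6 RPKM in WT replicate 3 and 76.5 in KO replicate 3, against 158 to 211 in the others. Precursor ribosomal RNA (Rn45s) was at 5526 RPKM in WT replicate 3 and 782 to 1143 in the others.

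**Figure D1:**
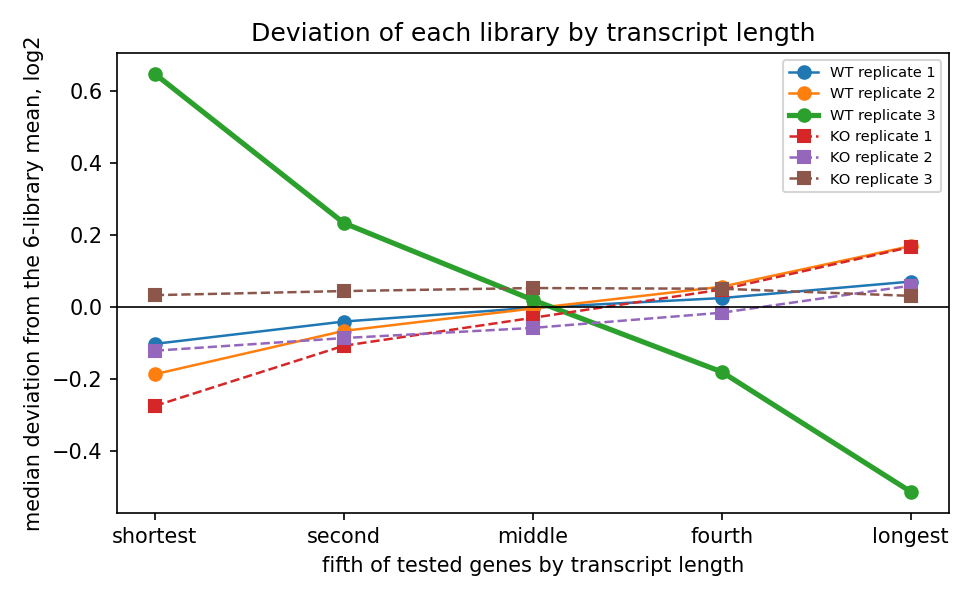
Median deviation of each library from the mean of all 6 libraries (y axis, log2) over genes grouped by transcript length (x axis, from shortest to longest), with solid lines for libraries labelled WT and dashed lines for those labelled KO. WT replicate 3 runs from 0.65 for the shortest transcripts to -0.51 for the longest, and the other libraries stay between -0.27 and 0.17.

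Tfam itself was measured in every library. Its level was 7.22, 8.44 and 5.72 RPKM in the libraries labelled WT and 5.92, 7.22 and 6.25 in those labelled KO, with means of 7.12 ± 1.36 and 6.46 ± 0.679 (SD, n = 3). The groups overlapped (exact two-sided permutation test, p = 0.7, where 0.1 is the smallest possible), and the log2 fold change was -0.11 (95% interval -0.52 to 0.29). A deletion of part of a gene can leave reads on the remaining exons, and these gene-level values do not separate exons. The level of Tfam therefore does not check the labels, and KO and WT below name libraries by their labels only.

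With all 6 libraries no single gene passed the limma test, and the 5 genes given next were chosen after their values were seen. Atf5, a transcription factor of the integrated stress response, was at 17.1 ± 1.78 RPKM in KO and 7.16 ± 1.29 in WT (n = 3 each), and Trib3, a pseudokinase induced in the same response, was at 7.80 ± 0.576 and 3.04 ± 1.04. Epor, the erythropoietin receptor, was at 113 ± 15.3 RPKM in KO and 274 ± 99.2 in WT. The glutathione transferase Gsta4 was at 2.39 ± 0.437 and 5.56 ± 0.387, and the linker histone Hist1h1a at 14.4 ± 3.05 and 36.0 ± 15.8. In each of these genes every KO library lay on the same side of every WT library. The log2 fold changes were 1.16 (SE 0.17) for Atf5, 1.16 (SE 0.22) for Trib3, -1.23 (SE 0.28) for Epor, -0.96 (SE 0.15) for Gsta4 and -1.21 (SE 0.31) for Hist1h1a. With limma, 0 of 8302 genes passed an adjusted p of 0.05, and the lowest adjusted p was 0.909. At an unadjusted p under 0.05 there were 100 genes, 62 higher and 38 lower in KO, where chance would give 415.1. With the replicate block 0 genes passed and 324 had an unadjusted p under 0.05, or 589 with length and GC trends also removed. In 4.54% of genes the groups did not overlap, where chance gives 10% for libraries that are not paired. Without WT replicate 3 the test called 1 gene, the small nucleolar RNA gene Snord67 (chosen after its values were seen), which was listed at 0 in WT replicates 1 and 2. Without KO replicate 2 it called 2 genes, Mir135a-1 and Snord88c, and without KO replicate 3 it called 1, Snord96a. When libraries were weighted by limma from the spread of these same values, 60 genes passed. The weight was 21.4 for WT replicate 1, 0.565 for WT replicate 2 and 0.0859 for WT replicate 3. The WT level in that fit therefore came almost wholly from WT replicate 1.

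**Figure D2:**
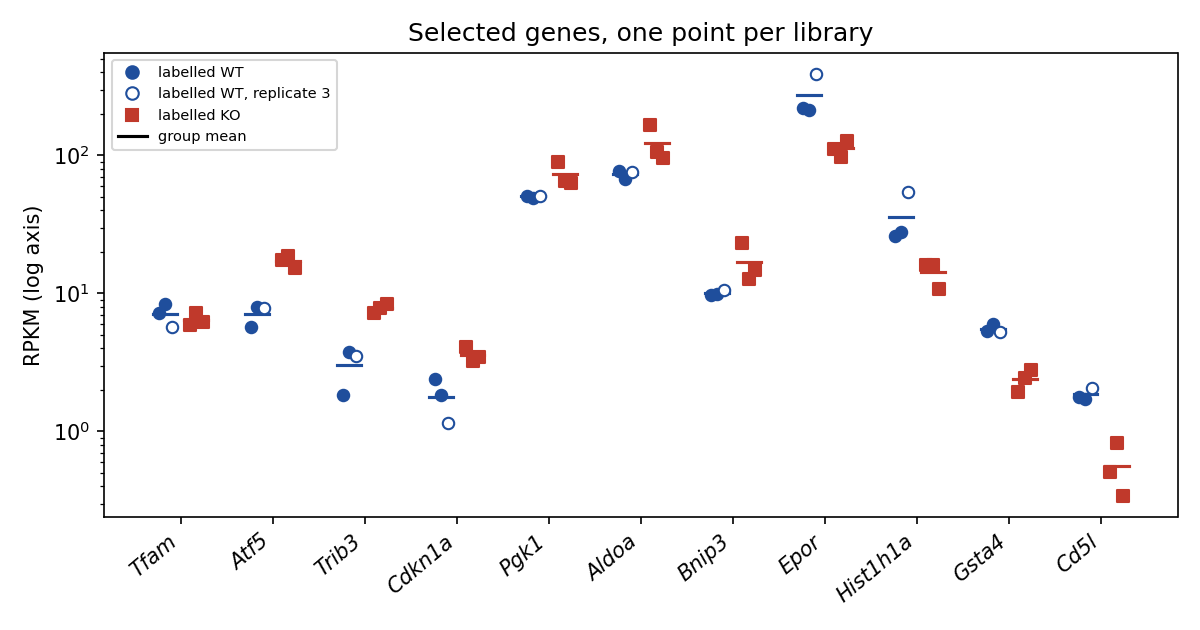
RPKM of 11 genes (y axis, log scale) in each library, with circles for libraries labelled WT (open for replicate 3), squares for those labelled KO and lines for group means. Tfam overlaps between the groups, whereas Atf5 lies at 15.2 to 18.7 RPKM in KO and 5.68 to 7.97 in WT, and Epor at 97.7 to 128 and 215 to 389.

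Among the gene lists, those of the integrated stress response, serine and one-carbon metabolism, glycolysis, hypoxia-inducible factor targets and p53 targets rose in the libraries labelled KO relative to other genes, by camera with the preset correlation. Each of these calls was lost with an estimated correlation (adjusted p = 0.868 with an estimated correlation for all 5), and that of the integrated stress response also with the replicate block (adjusted p = 0.127). In the integrated stress response list 8 of 15 tested members had a higher and 7 a lower fitted value, and the rise rested on few members. Atf5 and Trib3 passed when adjusted over the list alone and 0 over all genes. Atf4, the central transcription factor of this response, was at 322 ± 63.0 RPKM in KO and 414 ± 154 in WT, and its target Ddit3 at 39.3 ± 4.42 and 57.4 ± 36.2. WT replicate 3 held the highest level of both (591 and 99.0 RPKM), and without it the log2 fold change was -0.032 in place of -0.32 for Atf4 and 0.10 in place of -0.37 for Ddit3. The glycolysis list had 12 of 16 members with a higher fitted value. Pkm was at 31.4 ± 9.15 RPKM in KO and 15.8 ± 5.29 in WT, Aldoa at 123 ± 37.6 and 73.5 ± 5.13, and Pgk1 at 73.1 ± 15.0 and 50.5 ± 0.865, with the highest level of all 3 in KO replicate 1. Of the hypoxia-inducible factor targets 10 of 11 had a higher fitted value, among them Bnip3, a mitophagy receptor (17.0 ± 5.65 and 10.1 ± 0.479 RPKM), and Vegfa (5.25 ± 2.44 and 2.16 ± 1.18, with log2 fold changes of 0.98 and, without WT replicate 3, 0.65). In serine and one-carbon metabolism 11 of 13 had a higher fitted value, led by the proline synthesis enzyme Pycr1 (4.09 ± 0.733 and 2.56 ± 0.163 RPKM). Among p53 targets 8 of 10 had a higher fitted value, led by the cell cycle inhibitor Cdkn1a (3.61 ± 0.444 and 1.79 ± 0.625 RPKM), a gene named before the data were examined. In these last 4 lists 0 members passed over all genes and 0 when adjusted over the list alone. As defined, several of the lists that rose share members, so their shifts are not independent.

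By camera with the preset correlation, adjusted p was 0.000135 for hypoxia-inducible factor targets (median log2 fold change 0.25), 0.000672 for glycolysis (0.19), 0.0236 for serine and one-carbon metabolism (0.10), 0.0420 for the integrated stress response (0.10) and 0.0457 for p53 targets (0.11). With the replicate block p53 targets (adjusted p = 0.0808) no longer passed either. The integrated stress response was also lost without WT replicate 1 (adjusted p = 0.589), WT replicate 2 (0.358) or KO replicate 3 (0.336), glycolysis without WT replicate 2 (0.212), the serine list without WT replicate 1 (0.415) or KO replicate 2 (0.302), and p53 targets without WT replicate 2 (0.349) or KO replicate 1 (0.376). At a mean RPKM of at least 5 the integrated stress response, the serine list and p53 targets did not pass. No variance trend also ended the call of the integrated stress response, and no filter those of the serine list and p53 targets. The p53 call was lost as well with a pseudocount of 0.1, quantile normalization, scaling to the RPKM sum without globins and library weights. The medians moved with single libraries. That of the integrated stress response turned to -0.095 without KO replicate 3 and was 0.024, 0.056 and 0.23 without WT replicates 1, 2 and 3. For glycolysis the median was 0.13, 0.063 and 0.32 without WT replicates 1, 2 and 3 and 0.12 without KO replicate 1. For the serine list it was 0.28 and 0.18 without WT replicates 2 and 3 and 0.18, 0.023 and 0.16 without KO replicates 1, 2 and 3. For p53 targets it was 0.20 without WT replicate 1 or KO replicate 2 and 0.041 without WT replicate 3. With length and GC trends removed the median was 0.38 for glycolysis, 0.24 for the integrated stress response and 0.20 for the serine list.

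Replication-dependent histones fell in the libraries labelled KO, with 51 of 54 tested members at a lower fitted value and a median log2 fold change of -0.85. The camera adjusted p was 3.05e-23, and adjusted p = 0.868 with an estimated correlation. Hist1h1b was at 24.0 ± 7.29 RPKM in KO and 50.2 ± 18.6 in WT, and Hist1h2bl at 3.25 ± 1.34 and 14.3 ± 12.4. In 15 members every KO library lay below every WT library, and 0 passed over all genes or adjusted over the list alone. Histone genes are short, and WT replicate 3 held the highest level of Hist1h1a, Hist1h1b and Hist1h2bl. Without that library the median was -0.40 and the call held (adjusted p = 2.80e-23, and adjusted p = 0.0455 with an estimated correlation). Genes of S phase, when replication-dependent histone mRNAs are made, had 18 of 21 members at a lower fitted value and did not pass (median -0.15, adjusted p = 0.0635). With the replicate block the S phase list passed as lower (adjusted p = 0.0205, and adjusted p = 0.838 with an estimated correlation), as it did without KO replicate 3 (adjusted p = 0.00189), while without WT replicate 3 its median was -0.0044.

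Of the lists of nuclear genes for mitochondrial proteins, 6 also fell relative to other genes when all 6 libraries were used, and other mitochondrial lists did not pass. The calls of these 6 and of cytosolic ribosomal proteins were lost with an estimated correlation (adjusted p = 0.868 with an estimated correlation for each). The mitochondrial ribosome had 71 of 76 members at a lower fitted value (median -0.28), complex I 35 of 37 (-0.39), complex III 9 of 9 (-0.38), complex IV 15 of 17 (-0.32), ATP synthase 16 of 17 (-0.36) and mitochondrial protein import 23 of 26 (-0.21). Cytosolic ribosomal proteins had 80 of 80 at a lower fitted value (-0.23, but 0.02 after quantile normalization). Scaling to the RPKM sum without globins moved the median of all genes from -0.02 to 0.17 and that of protein import to 0.0043, still lower relative to other genes. The adult globins were listed at 0, so this scaling divided mainly by the RPKM sum, which was highest in WT replicate 3 (815524). In these 7 lists 0 members passed over all genes and 0 adjusted over the list alone. Camera adjusted p was 5.20e-09 for the mitochondrial ribosome, 3.66e-05 for complex I, 0.0158 for complex III, 0.0420 for complex IV, 0.00455 for ATP synthase, 0.0138 for protein import and 0.000371 for cytosolic ribosomal proteins. With length and GC trends removed, complex III (adjusted p = 0.0692), complex IV (0.275), protein import (0.0692) and cytosolic ribosomal proteins (median -0.027, adjusted p = 0.459) did not pass. Cyc1, cytochrome c1 of complex III, was at 179, 164 and 303 RPKM in the WT libraries and 143, 154 and 190 in the KO libraries. Without WT replicate 3 the 6 mitochondrial lists had medians of -0.01 to 0.06 and none passed, and cytosolic ribosomal proteins turned to a rise (median 0.16, adjusted p = 8.10e-08, and adjusted p = 0.991 with an estimated correlation). Without KO replicate 1, complex III (adjusted p = 0.137), complex IV (0.400), ATP synthase (0.0614), protein import (0.435) and cytosolic ribosomal proteins (0.323) did not pass, nor did complex IV without KO replicate 2 (0.0949). With library weights each of the 7 calls but that of the mitochondrial ribosome was lost. Quantile normalization also ended the calls of complex IV and cytosolic ribosomal proteins, and a mean RPKM of at least 5 that of protein import.

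**Figure D3:**
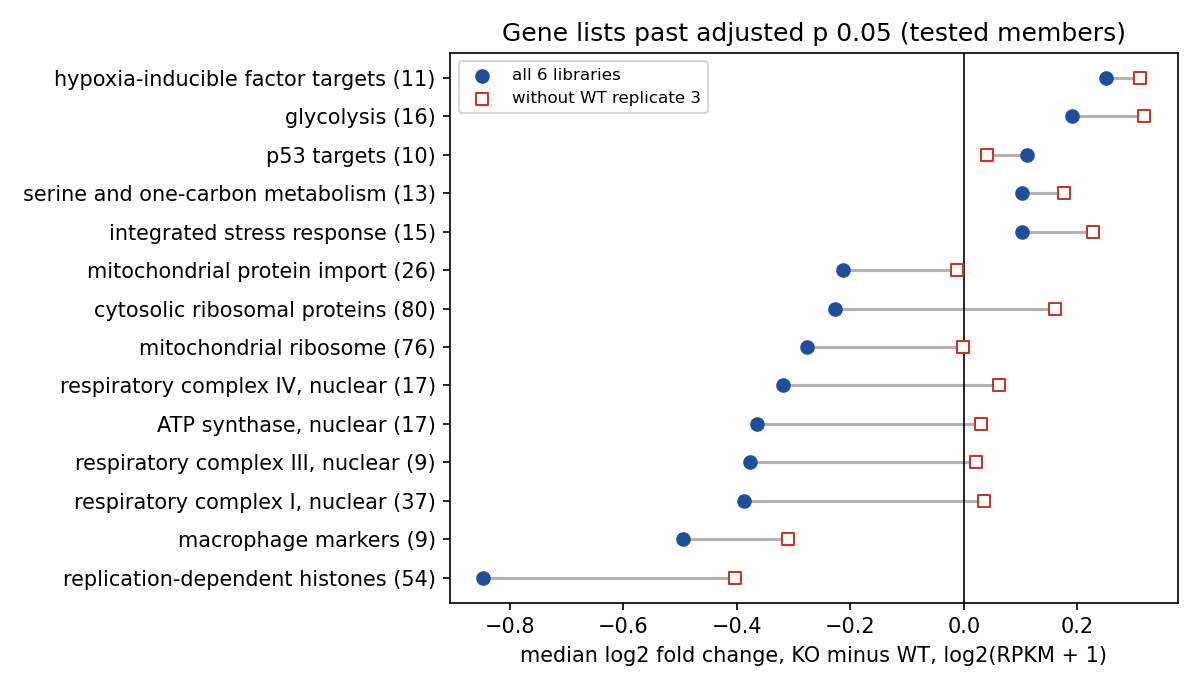
Median log2 fold change, KO minus WT, of the 14 gene lists past an adjusted p of 0.05 (x axis, log2(RPKM + 1) scale), with filled circles for all 6 libraries, open squares for the fit without WT replicate 3, and the number of tested members in brackets. Histones stay lower at -0.40, and the respiratory chain, import and ribosome lists move to between -0.01 and 0.16.

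The erythroid program showed no list past the threshold. Erythroid transcription factors (15 tested members), heme synthesis (13), red cell membrane and skeleton (16), late maturation (16), early progenitor genes (5), erythropoietin signalling targets (9) and iron handling (16) had camera adjusted p of 0.448 to 0.786. Without WT replicate 3, late maturation passed as higher (adjusted p = 0.0208) and early progenitor genes (0.0302) and erythropoietin signalling targets (0.0196) as lower, with adjusted p = 0.920 to 0.991 with an estimated correlation. Epor is a member of the last 2 lists, with a log2 fold change of -1.23 when all libraries were used. In that fit 4 of 5 early progenitor genes and 5 of 9 erythropoietin signalling targets had a higher fitted value. These calls are therefore not independent of the Epor value, and the lists were not tested without Epor. Early progenitor genes, whose median with all libraries was 0.04 against a downward test direction, also passed as lower without KO replicate 2 (median -0.22, adjusted p = 0.0202). Gata1, a master regulator of the lineage, was at 199 ± 42.2 RPKM in KO and 248 ± 75.3 in WT, and the row of Klf1, shared with Dnase2a, at 486 ± 128 and 695 ± 394. Bcl11a, a repressor of embryonic globin genes, was at 15.1 ± 3.72 and 15.3 ± 1.63. Alas2, the first enzyme of heme synthesis in red cells, was at 2607 ± 680 and 3440 ± 1809, with 5510 in WT replicate 3. Tfrc, the transferrin receptor, was at 865 ± 92.0 and 795 ± 170, and the mitochondrial iron importer Slc25a37 at 2940 ± 371 and 2794 ± 315. The mitophagy receptor Bnip3l was at 302 ± 50.2 and 292 ± 79.4, and the histone deacetylase Hdac1 at 62.6 ± 11.9 and 72.6 ± 14.3. Several of these differences shrank, turned or grew without WT replicate 3. The log2 fold change without it was -0.064 in place of -0.30 for Gata1, 0.025 in place of -0.41 for the row of Klf1 and Dnase2a, 0.093 in place of -0.31 for Alas2, -0.035 in place of 0.14 for Tfrc, -0.026 in place of 0.071 for Slc25a37, -0.059 in place of -0.21 for Hdac1 and 0.28 in place of 0.069 for Bnip3l. Embryonic globins overlapped between groups (adjusted p = 0.203, and 0.0104 as higher in KO without WT replicate 1). Hba-x was at 230, 266 and 101 RPKM in KO and 158, 56.7 and 66.4 in WT, Hbb-y at 887, 1107 and 442 and at 1013, 277 and 240, and Hbb-bh1 at 1014, 752 and 907 and at 1441, 708 and 1221. None of these genes passed the limma test, with or without the replicate block. Within every numbered pair Hba-x was higher in KO, and Gata1, the row of Klf1 and Dnase2a, Alas2 and Hdac1 were lower. The pairs differed in direction for Hbb-y, Hbb-bh1, Bcl11a, Tfrc, Slc25a37 and Bnip3l. The pairing was inferred from these same libraries, and with so few pairs a shared direction is common by chance. Kit, Bdh1 and Ppargc1a had a mean RPKM below 1 and were not tested. Their levels were 0.298 ± 0.181 in KO and 0.276 ± 0.104 in WT for the stem cell factor receptor Kit, 0.728 ± 0.334 and 0.585 ± 0.143 for Bdh1, and at most 0.0126 in any library for Ppargc1a.

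Transcripts of other cell types were also measured. Macrophage markers fell in the libraries labelled KO, with 9 of 9 tested members at a lower fitted value and a median log2 fold change of -0.49. The list had a camera adjusted p of 6.74e-07, and adjusted p = 0.868 with an estimated correlation. Cd5l, a secreted macrophage protein, was at 0.560 ± 0.248 RPKM in KO and 1.86 ± 0.185 in WT, and passed when adjusted over the list alone. It lay near the filter of a mean RPKM of at least 1, with every KO library below 1. Marco also lay near the filter, at 0.730 ± 0.525 RPKM in KO and 1.45 ± 0.146 in WT. Both passed the filter through their WT values. The marker Cd68 shares its row with Eif4a1, so that row cannot be read as macrophage RNA alone. C1qb was at 1.99 ± 0.615 and 3.90 ± 1.87, with 6.05 in WT replicate 3. The median of the list was -0.31 without WT replicate 3, -0.32 without KO replicate 3 and -0.28 with length and GC trends removed, and the call held in each. Megakaryocyte markers (adjusted p = 0.996) were low in both libraries numbered 3. Pf4, a platelet chemokine, was at 4.67 RPKM in WT replicate 3 and 1.17 in KO replicate 3, against 18.3 to 26.8 in the other libraries. Hepatocyte markers (adjusted p = 0.706) were lowest in KO replicate 3, where albumin was at 4.09 RPKM against 9.57 to 39.1 elsewhere. Neutrophil markers (adjusted p = 0.308) were highest in WT replicate 3, with S100a8 at 83.6 RPKM against 10.8 to 28.5. Without KO replicate 3, hepatocyte (median 0.53, adjusted p = 0.00189) and megakaryocyte markers (median 0.66, adjusted p = 0.0170) passed as higher in KO, while without KO replicate 2 hepatocyte (median -0.59, adjusted p = 0.000109) and neutrophil markers (-0.57, 0.00298) passed as lower. The neutrophil median, -0.27 with all libraries, turned to 0.35 without WT replicate 3 and did not pass there (adjusted p = 0.167). Without WT replicate 3 megakaryocyte markers passed as lower (median -0.53, adjusted p = 0.0212, and adjusted p = 0.991 with an estimated correlation). The macrophage call was lost without both libraries numbered 3 (adjusted p = 0.0725). Endothelial, mesenchymal, mast cell and lymphoid lists had fewer than 3 tested members.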

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

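Length and GC removal, omission of both libraries numbered 3, omission of small RNA rows and an estimated correlation combined with length and GC removal or with omission of WT replicate 3 were chosen after seeing the data. With limma, 0 genes passed with all libraries, with the replicate block and under each pseudocount, filter, scaling, minimum fold change and length correction run, with 47 to 589 at an unadjusted p under 0.05 and 100 in the fit of all libraries. Library weights called 60 genes, with the largest weight on WT replicate 1, and omission of both libraries numbered 3 called 2. Leaving out each library gave 0 to 2 genes. Tfam passed in none of these, with log2 fold changes of -0.24 to 0.0032 when each library was left out and 0.078 after scaling to the RPKM sum without globins, a scaling that moved the median of all genes from -0.02 to 0.17. With the adult globins listed at 0, that scaling divided mainly by the RPKM sum, which was highest in WT replicate 3. The replicate block ended the calls of the integrated stress response and p53 targets, added S phase and changed no other call, with 12 lists in place of 13 and 1 cell type list as before. Lists other than cell types numbered 8 with library weights, and 7 (without KO replicate 1) to 14 (without KO replicate 3) when each library was left out. Of all 14 lists called, 5 were higher and 9 lower, against 6 and 7 of 13 after quantile normalization. The balance turned to 9 higher and 5 lower without WT replicate 3, with 7 of the 14 lists shared in direction, and to 9 higher and 3 lower without both libraries numbered 3. With an estimated correlation 0 lists and 0 cell type lists passed, as with fry and as with an estimated correlation after length and GC removal. With an estimated correlation and WT replicate 3 left out, 1 list (histones) and 0 cell type lists passed. Cell type lists numbered 3 with no filter, 0 at a mean RPKM of at least 5, and 1 to 3 when each library was left out. At a mean RPKM of at least 5 the macrophage list had fewer than 3 tested members, so its call was not tested there.

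Cytosolic ribosomal proteins changed direction, with medians of 0.023 after quantile normalization, 0.0059 with library weights, 0.044 without both libraries numbered 3, and -0.46 to 0.16 when each library was left out. The same ranges were -0.62 to 0.036 for complex I, -0.56 to 0.021 for complex III, -0.59 to 0.062 for complex IV, -0.64 to 0.031 for ATP synthase, -0.43 to -0.0011 for the mitochondrial ribosome and -0.30 to -0.011 for protein import. The upper end of each of these 7 came without WT replicate 3, and an estimated correlation there left these medians as they were. Camera compares a list with other genes, so it gave an upward direction at medians just below 0. Hepatocyte markers ranged from -0.59 to 0.53, with 0.46 without both libraries numbered 3, and megakaryocyte markers from -0.53 to 0.66. Length and GC removal brought complex I to -0.15, ATP synthase to -0.17 and the mitochondrial ribosome to -0.15 with their calls kept, ended the calls of complex III, complex IV, protein import and cytosolic ribosomal proteins, and added S phase. Beyond this correction the cause was not tested. Of 1528 values of named genes under alternatives that passed in neither fit, 27 had the other sign. Many of these genes were chosen after the fit for a small p, which favours a stable sign. Among tested genes named beforehand, Tfam, Alas2, Bcl11a, Bnip3l, Ddit3, Hbb-y, Hdac1, Slc25a37, Tfrc and the Klf1 row took both signs across alternatives. Hba-x, Hbb-bh1, Gata1, Atf4 and Cdkn1a kept theirs. Absolute depth is unknown, and WT replicate 3 has no relative depth, so no limit on low genes can be given.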

Other observations

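The tests of explanations for the 3 patterns weighed here, the removal of length and GC trends, and an estimated correlation combined with it or with omission of WT replicate 3, were chosen after the result was seen, while the lists, their camera tests, the fits that leave out a library and the counts of other splits for genes, lists and cell types were not. Outside the lists already described, nuclear genes for mitochondrial DNA maintenance and transcription differed little, with a median log2 fold change of -0.04 over 18 tested members (camera adjusted p = 0.565). Polrmt, the mitochondrial RNA polymerase, had a log2 fold change of 0.07 (SE 0.14). With all 6 libraries none of the following lists passed: complex II (adjusted p = 0.203), mitochondrial biogenesis regulators (0.571), the mitochondrial unfolded protein response (0.451), the TCA cycle (0.590), fatty acid oxidation (0.732), ketone body metabolism (0.786), fission and fusion (0.706) and autophagy and mitophagy (0.565). Autophagy and mitophagy passed as higher without WT replicate 3 (adjusted p = 5.65e-05, and adjusted p = 0.920 with an estimated correlation). Pink1, a kinase that marks damaged mitochondria, was at 46.8, 47.2 and 63.6 RPKM in the libraries labelled KO and 30.9, 35.6 and 83.1 in those labelled WT. Cytosolic aminoacyl-tRNA synthetases (0.243), apoptosis regulators (0.706), G2 and M phase (0.376), histone acetylation enzymes (0.376), the mTORC1 pathway (0.996), antioxidant genes (0.809), interferon-stimulated genes (0.437) and cholesterol synthesis (0.809) did not pass either. Leaving out a library changed 3 of these, with interferon-stimulated genes higher without WT replicate 3 (adjusted p = 0.00707, and adjusted p = 0.991 with an estimated correlation). The synthetases were lower without KO replicate 2 (adjusted p = 0.0390) and G2 and M phase without KO replicate 3 (adjusted p = 0.0260), where an estimated correlation was not run.

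Other genes stood apart between the groups without passing the limma test (adjusted p = 0.909 or more in the fit of all libraries). Sprr2a1, a small proline-rich protein gene with close paralogs that could share its reads (adjusted p = 0.909), was at 31.7, 108 and 186 RPKM in the libraries labelled KO and 358, 265 and 325 in those labelled WT. Ndrg2 was at 14.7, 7.88 and 3.70 and at 2.27, 1.75 and 2.47, and Ndufa4l2, a known hypoxia-responsive gene, at 3.91, 1.31 and 1.19 and at 0.140, 0.330 and 0.511. Xist, expressed from the inactive X chromosome, was at 93.1, 122 and 59.3 RPKM in WT replicate 1, KO replicate 1 and KO replicate 3 and below 0.1 in the others, where the Y-linked Eif2s3y was at 34.7, 39.5 and 48.8. By these genes the sexes were not split alike between the groups. The list of sex-linked genes pools Xist with Y-linked genes, which move in opposite directions between the sexes. Its camera test (adjusted p = 0.748) therefore cannot show whether sex differs between the groups.

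With 10 splits of 6 libraries into 3 and 3, no share under 0.05 can be reached. The real split called 0 genes and the highest other split 3, so all 10 splits gave as many. It called 13 lists other than cell types, 4 of the 10 splits gave as many or more, itself included, and the highest other gave 16. It called 1 cell type list, where all 10 splits gave as many and the highest other 3. The split that set WT replicates 1 and 3 and KO replicate 3 against the rest had 855 genes at an unadjusted p under 0.05 against 100 for the real split. It is the highest of the 9 other splits, whose lowest was 15, and was not tested against chance. Among the 4 splits that part every numbered pair, the other 3 called 5 to 13 lists.

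WT replicate 3 lay apart from the other 5 libraries. Its deviation from them had a rank correlation across genes of -0.61 with transcript length, where the highest of the others was 0.39 in KO replicate 1, so a loss of long transcripts, as from shorter RNA or another library size range, may account for part of the distance. The length and GC trend as fitted did not remove all of it, because the SD of its deviation was 0.48 after removal against at most 0.28 in the other libraries. The lengths were those of the longest GENCODE vM21 transcript, which may not be the transcripts expressed here, and the depth of WT replicate 3 is unresolved. The remaining SD therefore cannot show how much of the distance length made up. What made up the rest stays open, and no biological explanation was tested.

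Epor was lower in every library labelled KO. The log2 fold change was -0.95 without WT replicate 3 (95% interval -1.35 to -0.56, limma adjusted p = 0.750). With length and GC removed it was -0.99 (-1.29 to -0.69, adjusted p = 0.851, and -1.23 to -0.75 with the replicate block). The difference thus remained without that library and without the fitted trend. Epor was chosen after its values were seen in these same libraries, and the intervals are not corrected for that choice. They therefore cannot exclude either cause. A candidate explanation is a Cre driver inserted in Epor that leaves a single intact allele, which would give -1. That value lies inside the wide interval with all libraries (-1.23, -1.90 to -0.56), which is not corrected for the choice either. Other explanations could also give it. The labels name no driver, reads of Cre or of each allele were not analysed here, and a response to Tfam loss was not tested. The adjusted p of 0.909 with all libraries leaves chance open. It was 0.0157 with library weights, where the WT level came almost wholly from WT replicate 1, and up to 1 in other alternatives. The list of 9 erythropoietin targets, Epor included, had a median of 0.016 with all libraries (adjusted p = 0.494) and passed as lower without WT replicate 3 (median -0.094, adjusted p = 0.0196, and adjusted p = 0.920 with an estimated correlation). Because the receptor Epor is itself a member, this call is not separate evidence, and the list was not tested without it.

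The integrated stress response, glycolysis and hypoxia-inducible factor lists were higher in the libraries labelled KO by camera with the preset correlation. As defined, the hypoxia-inducible factor list shares a member with each of the other lists, so the 3 lists are not independent. The highest adjusted p of the 3 was 0.000782 with length and GC removed (0.0105 with the replicate block), 2.34e-08 without WT replicate 3 and 0.00722 without KO replicate 1. At that correlation the calls thus remained without the fitted trend and without either library. These fits share libraries with the fit that picked the lists, so they cannot exclude those causes. With an estimated correlation adjusted p was 0.521 with length and GC removed and 0.533 without WT replicate 3. An estimated correlation was not run without KO replicate 1. The integrated stress response was lost with the replicate block (adjusted p = 0.127) and without WT replicate 1 (0.589), WT replicate 2 (0.358) or KO replicate 3 (0.336). Its call was also lost at a mean RPKM of at least 5 and with no variance trend. Glycolysis was lost without WT replicate 2 (0.212) and its median was 0.12 in place of 0.19 without KO replicate 1. Over the camera alternatives the highest adjusted p of each list was 0.868, with an estimated correlation and all libraries. The 3 lists were picked because the real split called them, so it counts by construction among the 3 of 10 splits that called all 3 in a single direction, and 10 splits are too few for a share under 0.05. Whether a response to Tfam loss, correlated genes or chance may underlie these lists stays open.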
